A study of Mus musculus with 4 samples.

How the data were processed

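RNA was measured in sorted nuclei of excitatory neurons (2 libraries) and inhibitory neurons (2 libraries) from adult wild-type mouse brain without the olfactory bulb. Per the labels' protocols, RNA was extracted from the sorted nuclei, depleted of ribosomal RNA and made into strand-specific libraries, which were sequenced as read pairs. The authors deposited 1 table of TPM values (transcript abundances scaled to a fixed total) with 1 column per library, in which transcript length and depth have been divided out. Per the submitters' processing notes, the tools were fastp 0.23.4, HISAT2 2.2.1, Bowtie2 2.3.5 and StringTie 2.2.1 with the genome build mm10. The role and order of these tools, the annotation release and the use of strand in counting are not given in the sources used here. Each column summed to between 999833 and 999891. TPM keeps no depth, so depth per library is unknown, no counting interval was computed, and a value of 0 is reported only as listed at 0.

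The table listed 55487 genes by Ensembl identifier and symbol, and 114 symbols stood under more than 1 identifier. Positions, strands and overlaps came from the GENCODE mouse release M21, whose identifiers matched 55227 of the listed genes and 99.7% of those tested. The microRNA genes within other genes were placed by these coordinates. Groups and replicate numbers came from the sample titles, and each column was matched to its sample by the column name in the sample description. In each group, the libraries differed in nearly every gene, with 89 identical log2 values between the excitatory libraries and 93 between the inhibitory ones among 26055 genes. No column was therefore a copy of another. Repeat libraries of the same sample would differ likewise, so this does not show that the samples were separate. Each library was counted as a replicate by its title.

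Values were taken as log2(TPM + 1), a pseudocount of 1, for the 26055 genes with at least 1 TPM in at least 2 of the 4 libraries. Excitatory was compared with inhibitory by limma 3.58.1 in R 4.3.3 (linear model, moderated test with a variance trend, 2 residual degrees of freedom and a prior worth 4.04). P-values were two-sided and adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called higher in the group where they stood higher. A fold is the ratio of mean TPM values, while the log2 fold change is the difference of mean log2(TPM + 1) values. Groups did not overlap for 56.2% of the tested genes, against 33.3% by chance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

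Gene lists were tested as sets. There were 37 lists with 690 entries and 663 distinct genes, of which 602 were tested. The lists covered neuron types, non-neuronal cells, the EGR family, immediate early genes, DNA methylation, histone modification, receptors, channels, synapse genes and checks of the libraries. They were written from general knowledge, and 24 genes were on more than 1 list. For each list, calls were counted over all genes tested and again with p-values adjusted over the list alone. The 35 lists with at least 5 tested members were set against all other genes by camera with a preset correlation of 0.01 between genes, and again with the correlation estimated for each list. Camera called 18 lists with the preset correlation and 0 with the estimated one, where the smallest adjusted p was 0.180. With an estimated correlation, camera tests on the 2 residual degrees of freedom of the fit, which weakens it for every list. The striatal (0.00127) and Purkinje (-0.028) lists had estimated correlations below the preset one and lost their calls too. A call lost in this setting therefore does not show that correlation between genes made it. Other called lists had estimates well above the preset one, such as astrocyte (0.605), postsynaptic density (0.417), thalamic (0.242) and inhibitory identity (0.203). If these estimates hold, the p-values of such lists with the preset correlation are too small. Fry, which tests whether the members of a list move on balance in the same direction and makes no comparison with other genes, called 18 of the 35 lists, and 29 for movement in either direction.

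The genes named were taken by a rule. It took the 10 genes with the largest log2 fold change in each direction among called genes whose groups did not overlap, whose higher mean was at least 5 TPM and whose symbol was not a predicted gene, clone or mitochondrial name. It also took Egr1 to Egr4, Nab1 and Nab2, the 4 members of each list with the smallest p, and the sex-linked and mitochondrial genes as checks. Some genes of the rule are left out of the text, and each gene outside it is said to be singled out after its values were seen, except that members of the 2 sets written for the closing observations were picked from those sets by their values. The rule, the groups, the lists, the test and the alternatives listed next were fixed before the data were examined.

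The alternatives were a pseudocount of 0.1, no filter on low values, a filter of at least 5 TPM in 2 libraries, median ratio scaling, quantile normalization, rescaling without mitochondrial genes and the 20 most abundant genes, no trend in the variance prior, the replicate number as a block, leaving out each library in turn, and a test against a log2 change of 1. Fits without 1 library had 1 residual degree of freedom and assumed that the lone library varies like the other group. Median ratio scaling moved the median log2 fold change of all tested genes from -0.07 to -0.01. After the data were seen, a restriction to protein-coding genes and the removal of a trend with gene length were added. The protein-coding genes were rescaled to the same total before the filter, which left 15251 tested against 14602 in the main fit. Removal of the length trend, fitted in each library, also moved the median log2 fold change of all tested genes to 0.003. For the observations that close the text, a set of 17 markers of glutamatergic neurons from outside the telencephalon and a set of 12 T cell genes were written before their values were looked up.

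The procedure was tested on simulated data with the gene means of these libraries. Each gene's variance was drawn from the prior that limma fitted, with independent normal noise, so the simulation follows the model of the test. It held no correlation between genes and no deviation of a whole library. Its rates therefore hold under that model and do not give the error rates in these libraries. With 200 changed genes among 26055, drawn from genes above 5 TPM, limma recovered 15% of those changed by 1 and 75% of those changed by 2 on the log2 scale, with 1 false call in 91. With 3200 changed genes, 70% and 96% were recovered, with 130 false calls in 3049. With no changed gene it made 0 calls.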

Results

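RNA was measured in nuclei of excitatory and inhibitory neurons that had been separated by fluorescence-activated sorting, a method that collects single labelled nuclei. The nuclei came from the brains, without the olfactory bulb, of adult wild-type mice. There were 2 libraries of excitatory nuclei and 2 of inhibitory nuclei, all labelled as 1 batch, and the markers used in the sort are not given in the sources used here. Values were TPM, transcript abundances scaled by the authors to the same total in each library. TPM keeps no sequencing depth, so the depth of each library is unknown. Each library listed between 32207 and 32836 genes above 0. The 10 genes most abundant on average took between 19.6% and 24.0% of the TPM. Libraries of the same group correlated at Pearson r = 0.967 (excitatory) and 0.968 (inhibitory) across the 26055 genes tested. Libraries of different groups correlated at 0.916 to 0.923, across genes that are not independent replicates. Male-specific transcripts were present in all 4 libraries, with Ddx3y between 36.8 and 49.4 TPM, while Xist, the X inactivation RNA, stood at or under 0.392 TPM in each. TPM values are means ± SD over n = 2 libraries. Log2 fold changes are excitatory over inhibitory on the log2(TPM + 1) scale with standard errors, a scale that understates changes of low genes.

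The comparison between excitatory and inhibitory nuclei addressed which transcripts set these populations apart, in a study concerned with the transcription factor EGR1 and epigenetic regulation in neuron types. Slc17a7, the vesicular glutamate transporter of cortical and hippocampal neurons, stood 6.51-fold higher in excitatory nuclei (366 ± 1.46 against 56.2 ± 5.67 TPM). Gad1, which encodes an enzyme that makes GABA, stood 5.21-fold higher in inhibitory nuclei. Egr1 was 1.75-fold higher in excitatory nuclei. Of marker genes tested, 19 of 20 for striatal, 9 of 12 for Purkinje and 8 of 11 for thalamic neurons were higher in inhibitory nuclei. In all, 1414 genes were higher in excitatory and 1725 higher in inhibitory nuclei among 26055 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 855 and 1199 differed by at least 1 on the log2 scale. With any 1 library left out (excitatory replicate 1 or 2, or inhibitory replicate 1 or 2), limma had 1 residual degree of freedom and called 0 genes (smallest adjusted p between 0.0545 and 0.0664), with 5658, 5812, 5321 and 5311 genes at an unadjusted p under 0.05. All 3139 called genes kept their direction in each of these fits, though they had been picked by a fit that used the same libraries. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples. An exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333.

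Among the genes named for the size of their change, those higher in excitatory nuclei included a transcription factor of the dorsal telencephalon. Smoc2, a secreted calcium-binding matrix protein (chromosome 17, 14279506 to 14404790, plus strand, mm10), reached 27.0 ± 1.57 against 0.941 ± 0.313 TPM, a log2 fold change of 3.86 ± 0.25 (adjusted p = 0.00165). Emx1, a homeobox factor of the dorsal forebrain, stood at 3.46 ± 0.32, and the zinc finger gene Ovol2 at 3.43 ± 0.28. Cd34, which encodes a cell surface sialomucin, stood at 51.0 ± 9.70 against 3.33 ± 0.264 TPM. Psrc1, a microtubule-associated protein, stood at 24.7 ± 2.98 against 1.51 ± 0.805 TPM and the hexokinase-like gene Hkdc1 at 16.9 ± 5.57 against 0.701 ± 0.0304 TPM. The serine protease gene Fap stood at 12.1 ± 3.08 against 0.278 ± 0.0631 TPM. Trbj1-1, a joining segment of the T cell receptor beta locus, had 8.67 ± 1.73 TPM in excitatory libraries and was listed at 0 in both inhibitory libraries.

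Of the genes named for their size of change toward inhibitory nuclei, Mir3967 led, at 17.98 ± 3.82 TPM in inhibitory libraries and listed at 0 in both excitatory ones. Mir3967 (chromosome 2, 22654283 to 22654350, plus strand) lies inside an intron of Gad2 on the same strand, with 0 of its 68 bases in Gad2 exons. Whether reads of unspliced Gad2 were counted for it is not given in the sources used here. Mir466l, likewise within an intron of Sfmbt2, had a log2 fold change of -3.38 ± 0.29. Erbb4, the neuregulin receptor of interneurons, stood at 8.66 ± 0.911 against 78.5 ± 5.99 TPM (log2 fold change -3.04 ± 0.15, adjusted p = 0.00149). Dlx6os1, a long noncoding RNA of the Dlx locus, stood at 7.34 ± 0.695 against 73.5 ± 1.28 TPM. It overlaps Dlx6 on the other strand, and whether the counting used strand is not given in the sources used here. The endoplasmic reticulum calcium pump gene Atp2a3 (-3.30), the Wnt pathway factor Lef1 (-3.18), Ankrd55 (-3.22), Abhd12b (-3.31) and Btbd11 (-2.95) completed this group of log2 fold changes. Tpi-rs9, a triosephosphate isomerase-related sequence, stood at -3.01, a value that is uncertain because such copies can share reads.

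**Figure D1:**
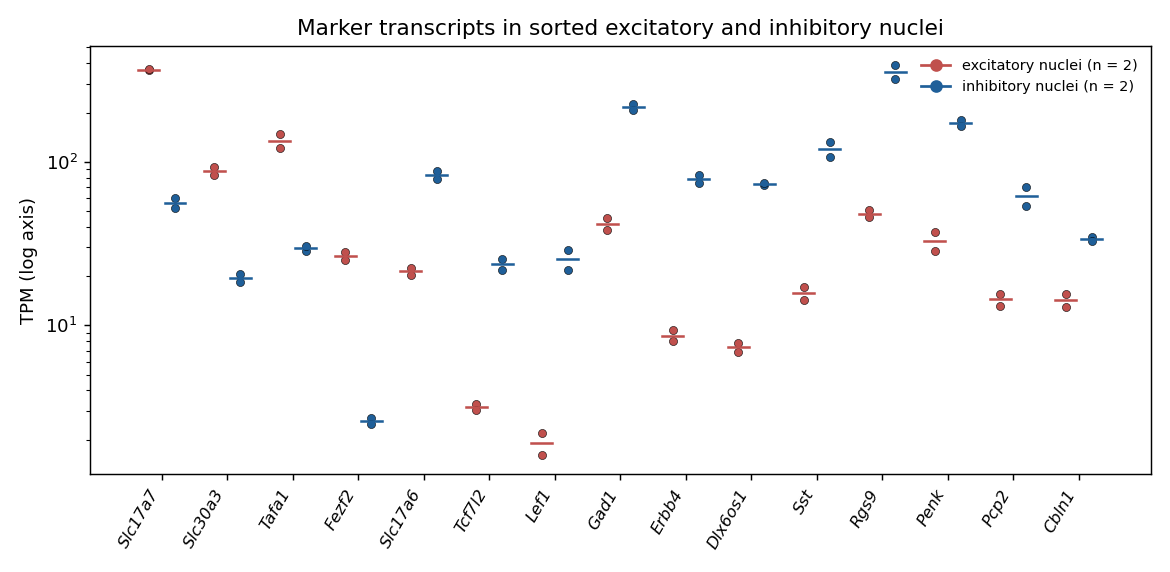
TPM (log axis) of 15 marker transcripts in each library, with excitatory nuclei in red and inhibitory nuclei in blue (n = 2 each, points for libraries and a line at the mean). Slc17a7 sits at 366 ± 1.46 TPM in excitatory libraries, whereas Slc17a6, the other glutamate transporter shown, sits higher in inhibitory libraries (83.2 ± 6.74 TPM).

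Among markers of excitatory identity, 16 of 18 tested genes were higher in excitatory nuclei, 1 was higher in inhibitory nuclei and 1 was not called (16 and 1 when adjusted over the list alone). The camera test gave this list an adjusted p = 1.49e-15, and adjusted p = 0.180 with an estimated correlation. Here and below, the estimated setting tests with 2 residual degrees of freedom. Besides Slc17a7, Slc30a3, the synaptic vesicle zinc transporter, stood at 87.8 ± 6.57 against 19.4 ± 1.63 TPM and the secreted protein gene Tafa1 at 135 ± 19.6 against 29.5 ± 1.34 TPM. The exception was Slc17a6, the vesicular glutamate transporter typical of thalamus and brainstem, at 21.3 ± 1.50 against 83.2 ± 6.74 TPM (log2 fold change -1.91 ± 0.13, adjusted p = 0.00176). Neurod1, singled out after its values were seen, stood at 14.1 ± 0.364 against 15.9 ± 1.30 TPM. It lies within Cerkl on the same strand, so the values of both genes are uncertain. In inhibitory nuclei, Slc17a7 stood at 15.4% of its excitatory level.

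Inhibitory identity markers were higher in inhibitory nuclei for 16 of 16 genes tested, of 18 listed (16 when adjusted over the list alone), with a median log2 fold change of -2.46. Lhx8 (0.0795 against 2.88 TPM) and Dlx5 (0.196 against 4.38 TPM), singled out after their values were seen, passed the filter only through the inhibitory libraries. The full count thus partly follows from the filter. Set against all other genes, the list had a camera adjusted p = 1.00e-15, and adjusted p = 0.180 with an estimated correlation. Gad1 reached 41.6 ± 4.84 against 217 ± 13.3 TPM (log2 fold change -2.36 ± 0.12, adjusted p = 0.00149). In excitatory nuclei, Gad1 stood at 19.2% and Dlx6os1 at 9.99% of their inhibitory levels. Interneuron subclass markers followed, with 13 of 24 higher in inhibitory, 2 higher in excitatory and 9 not called (19 and 2 when adjusted over the list alone). Camera returned adjusted p = 2.84e-08 for the list, and adjusted p = 0.180 with an estimated correlation. The neuropeptide genes Sst (15.8 ± 1.98 against 119 ± 16.8 TPM) and Tac1 (12.8 ± 3.40 against 102 ± 13.2 TPM), the RNA-editing family gene Adarb2 and the secreted glycoprotein gene Reln were among them. Lamp5 (1.12) and Satb1 (0.92), singled out after their values were seen, were the members higher in excitatory nuclei. Striatal projection neuron markers were higher in inhibitory nuclei for 19 of 20 genes (19 when adjusted over the list alone). As a set, these genes had a camera adjusted p = 1.07e-17, and adjusted p = 0.180 with an estimated correlation. The G protein regulator Rgs9 stood at 48.2 ± 3.04 against 354 ± 49.1 TPM and the enkephalin gene Penk at 32.6 ± 6.09 against 173 ± 10.8 TPM. The adenylyl cyclase gene Adcy5 stood at 46.1 ± 0.466 against 168 ± 0.368 TPM and the retinoic acid receptor gene Rarb at 15.9 ± 1.91 against 86.7 ± 6.30 TPM.

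Markers of cortical projection neurons went both ways. Of 20 tested, 6 were higher in excitatory, 4 higher in inhibitory and 10 not called (9 and 5 when adjusted over the list alone). The camera test gave this list an adjusted p = 0.00816, and adjusted p = 0.513 with an estimated correlation. Fezf2, the factor of deep-layer subcortical projection neurons, stood at 26.6 ± 2.23 against 2.61 ± 0.147 TPM, with the LIM domain gene Lmo4 at 1.83 and the receptor phosphatase gene Ptprk at 1.79 on the log2 scale. The members higher in inhibitory nuclei were Foxp2 (-1.37), Calb1 (-0.86) and, singled out after their values were seen, Syt6 (-0.97) and Pcp4 (-0.72, adjusted p = 0.0478, not called under 7 other settings, median ratio scaling and quantile normalization among them). Foxp2 is also on the striatal and Purkinje lists and Calb1 on the Purkinje list. Hippocampal projection markers were higher in excitatory nuclei for 6 of 16 genes and higher in inhibitory for 1, the calcium-binding protein gene Calb1 (9 and 1 when adjusted over the list alone). Set against all other genes, the list had a camera adjusted p = 2.47e-04, and adjusted p = 0.180 with an estimated correlation. Without the filter, or with a filter of at least 5 TPM, 3 were higher in excitatory nuclei. Mpped1 (1.50), the synaptic complement-like gene C1ql3 (2.24) and Lct (1.75, not called without the filter) led this list.

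Neuron markers from outside the telencephalon were higher in inhibitory nuclei, glutamatergic types included. Of thalamic markers, 8 of 11 were higher in inhibitory nuclei and 3 were not called (10 when adjusted over the list alone). Camera returned adjusted p = 2.84e-08 for the list, and adjusted p = 0.234 with an estimated correlation. Lef1 stood at 1.90 ± 0.409 against 25.4 ± 4.93 TPM and Tcf7l2, another Wnt pathway factor, at 3.17 ± 0.216 against 23.6 ± 2.74 TPM. Plekhg1 stood at 7.52 ± 0.153 against 32.2 ± 3.00 TPM. Slc17a6, described above among excitatory identity markers, is also among the thalamic calls. Of cerebellar granule cell markers, 9 of 15 were higher in inhibitory, 1 higher in excitatory and 5 not called (11 and 1 when adjusted over the list alone). As a set, these genes had a camera adjusted p = 4.35e-06, and adjusted p = 0.180 with an estimated correlation. They included the zinc finger genes Zic1 (-1.22) and Zic4 (-1.68), which overlap on opposite strands and are uncertain for that reason, and the synapse organizer gene Cbln1 (-1.20). Cerkl (1.32), singled out after its values were seen, was the member higher in excitatory nuclei and is the gene that contains Neurod1; its call was lost without the filter or with no trend in the variance prior. Reln, also an interneuron subclass marker, is among the granule cell calls. Purkinje cell markers were higher in inhibitory nuclei for 9 of 12 genes (12 when adjusted over the list alone). The camera test gave this list an adjusted p = 1.13e-09, and adjusted p = 0.180 with an estimated correlation. Pcp2 stood at 14.4 ± 1.73 against 61.7 ± 11.9 TPM and the carbonic anhydrase-related gene Car8 at 10.02 ± 0.809 against 43.5 ± 2.40 TPM.

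Of midbrain and hindbrain inhibitory markers, 8 of 12 were higher in inhibitory nuclei (12 when adjusted over the list alone). Set against all other genes, the list had a camera adjusted p = 3.46e-07, and adjusted p = 0.180 with an estimated correlation. The count was 4 without the filter or with a filter of at least 5 TPM. It was 13 with protein-coding genes only, where rescaling let more genes pass the filter. Slc6a5, the glycine transporter of glycinergic terminals, stood at 0.873 ± 0.441 against 10.3 ± 1.73 TPM and the glycine receptor gene Glra1 at 0.940 ± 0.179 against 10.4 ± 1.25 TPM, with the homeobox genes Lhx5 (-1.82) and Otx2 (-2.16, not called without the filter) beside them. Lhx5 and Otx2 were under 1 TPM in both excitatory libraries and passed the filter only through the inhibitory ones, so this count partly follows from the filter. Monoamine and acetylcholine genes were higher in inhibitory nuclei for 9 of 9 tested, of 14 listed (9 when adjusted over the list alone). Camera returned adjusted p = 1.54e-06 for the list, and adjusted p = 0.180 with an estimated correlation. Without the filter 4 were called, and 5 with a filter of at least 5 TPM. The dopamine transporter Slc6a3 stood at 0.342 ± 0.0315 against 6.01 ± 0.711 TPM and the choline transporter Slc5a7 at 0.423 ± 0.257 against 6.08 ± 1.27 TPM. Choline acetyltransferase (Chat) stood at 0.273 ± 0.0998 against 4.36 ± 1.28 TPM and tyrosine hydroxylase (Th) at 2.05 ± 1.51 against 13.8 ± 1.59 TPM, the last not called without the filter. Slc6a3, Slc5a7 and Chat were under 1 TPM in both excitatory libraries and passed the filter only through the inhibitory ones. The full count of calls on this list thus partly follows from the filter. Hypothalamic peptide genes were higher in inhibitory nuclei for 6 of 13 (8 when adjusted over the list alone). As a set, these genes had a camera adjusted p = 1.03e-04, and adjusted p = 0.180 with an estimated correlation. Without the filter on low values 2 were called. The members higher in inhibitory nuclei included oxytocin (Oxt, -2.88), vasopressin (Avp, -1.91), Tac2 (-2.25) and neurotensin (Nts, -1.71), of which Avp and Nts were not called without the filter. All 18 Hox genes listed were under 1 TPM in at least 3 libraries and were not tested.

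**Figure D2:**
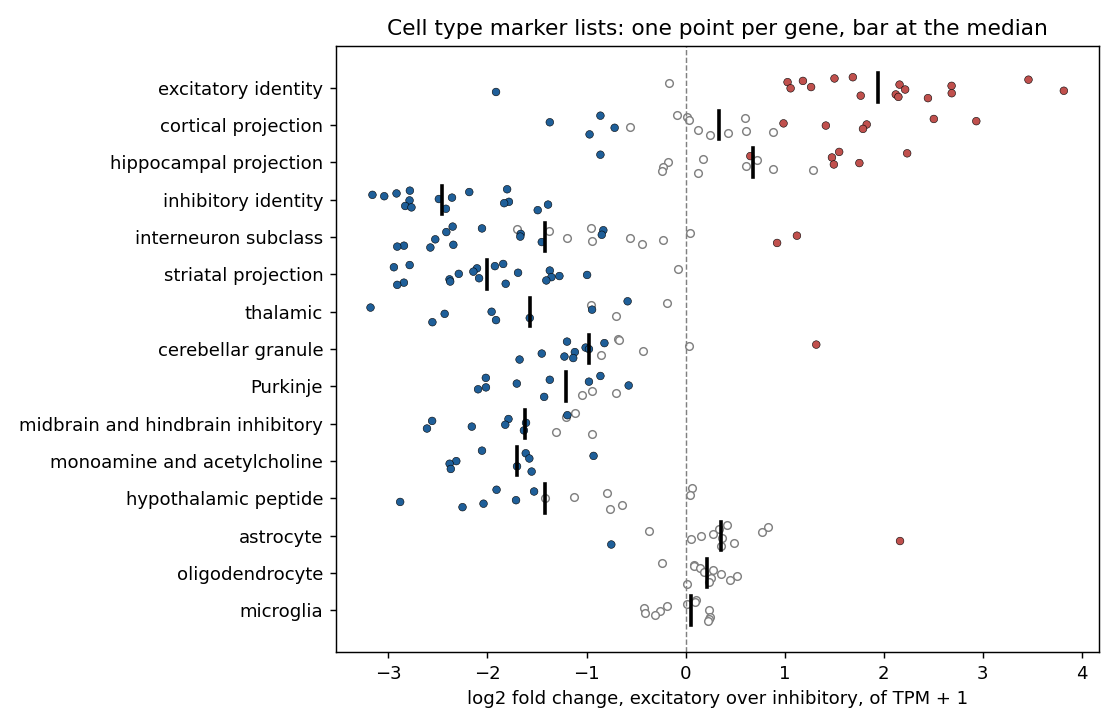
Log2 fold change (excitatory over inhibitory, TPM + 1) of each tested member of 15 cell type lists, with a bar at each list's median; filled points passed adjusted p under 0.05 (red higher in excitatory, blue higher in inhibitory) and open points did not. Medians run from -2.46 for inhibitory identity to 1.94 for excitatory identity, and thalamic markers lie at a median of -1.57.

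Few non-neuronal markers were called. Slc1a2, the main glial glutamate transporter, was higher in excitatory nuclei (394 ± 49.98 against 86.9 ± 2.68 TPM, log2 fold change 2.16 ± 0.12, adjusted p = 0.00154), and the bicarbonate cotransporter gene Slc4a4 was higher in inhibitory nuclei (100.4 ± 5.78 against 171 ± 29.8 TPM, not called without the filter or with no trend in the variance prior). These were the 1 and 1 calls among 13 astrocyte markers (1 and 1 when adjusted over the list alone). The camera test gave this list an adjusted p = 0.0336, and adjusted p = 0.747 with an estimated correlation. The astrocyte call was lost with a filter of at least 5 TPM (adjusted p = 0.0668), without excitatory replicate 1 (adjusted p = 0.196) or without inhibitory replicate 2 (adjusted p = 0.378). None of 12 oligodendrocyte markers was called by limma (0 toward excitatory and 0 toward inhibitory at an unadjusted p under 0.05, 0 when adjusted over the list alone; camera adjusted p = 0.0734). Camera called these markers toward excitatory without excitatory replicate 2 (adjusted p = 0.00442) or without inhibitory replicate 1 (0.00162), against adjusted p = 0.776 with an estimated correlation. The myelin genes Mbp and Mobp stood at 108 ± 12.9 against 85.7 ± 22.9 TPM and 40.6 ± 7.88 against 28.2 ± 6.73 TPM. None of 12 microglia markers was called (0 toward excitatory and 1 toward inhibitory at an unadjusted p under 0.05, 0 when adjusted over the list alone; camera adjusted p = 0.943). P2ry12 stood at 18.1 ± 0.610 against 22.7 ± 2.00 TPM. The microglia median was 0.05 while its mean (-0.04) and test pointed toward inhibitory. Among 9 oligodendrocyte precursor markers, 1 was higher in inhibitory nuclei, Lhfpl3 at -1.53 (1 when adjusted over the list alone; camera adjusted p = 0.997). The precursor median (0.21) also differed in sign from the mean (-0.09) and the test. Among 6 vascular markers, 1 was higher in excitatory nuclei, the matrix proteoglycan gene Dcn at 9.08 ± 1.62 against 2.16 ± 0.0167 TPM (not called without the filter on low values, 1 when adjusted over the list alone; camera adjusted p = 0.584). Of 6 ependymal and choroid plexus markers, 2 were higher in inhibitory nuclei, the chloride channel gene Clic6 (-2.21) and Otx2 (2 when adjusted over the list alone; camera adjusted p = 0.0734, 0.0287 toward inhibitory without inhibitory replicate 2, and adjusted p = 0.464 with an estimated correlation).

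Egr1, the activity-induced zinc finger transcription factor that the study's title names (chromosome 18, 34859823 to 34864984, plus strand, mm10), had 18.9 ± 0.189 against 10.8 ± 0.865 TPM, a log2 fold change of 0.75 ± 0.17 (limma adjusted p = 0.0427), and was higher in both excitatory libraries than in either inhibitory library. Egr3 was higher in excitatory nuclei by a similar amount (19.1 ± 1.21 against 10.1 ± 0.394 TPM, 0.86 ± 0.17, adjusted p = 0.0301). Egr4 stood at 6.10 ± 0.393 against 3.71 ± 0.0593 TPM (adjusted p = 0.190) and Egr2 at 1.58 ± 0.225 against 1.93 ± 0.617 TPM (adjusted p = 0.787), and neither was called. The EGR corepressor genes Nab1 (19.8 ± 1.86 against 19.3 ± 0.415 TPM) and Nab2 (17.1 ± 2.202 against 12.0 ± 2.02 TPM) were not called either. That made 2 of 6 EGR family genes higher in excitatory nuclei (2 when adjusted over the list alone). Set against all other genes, the list had a camera adjusted p = 0.0314, and adjusted p = 0.464 with an estimated correlation. Without the filter on low values the calls on Egr1 (adjusted p = 0.0718) and Egr3 (0.0585) were lost, which left 0 family calls, and without a trend in the variance prior that on Egr1 (0.0560) was lost. With any 1 library left out, where no gene at all was called, the log2 fold change of Egr1 stayed between 0.68 and 0.83. The family's camera call was lost without excitatory replicate 1 (adjusted p = 0.0556) or inhibitory replicate 2 (0.0549).

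**Figure D3:**
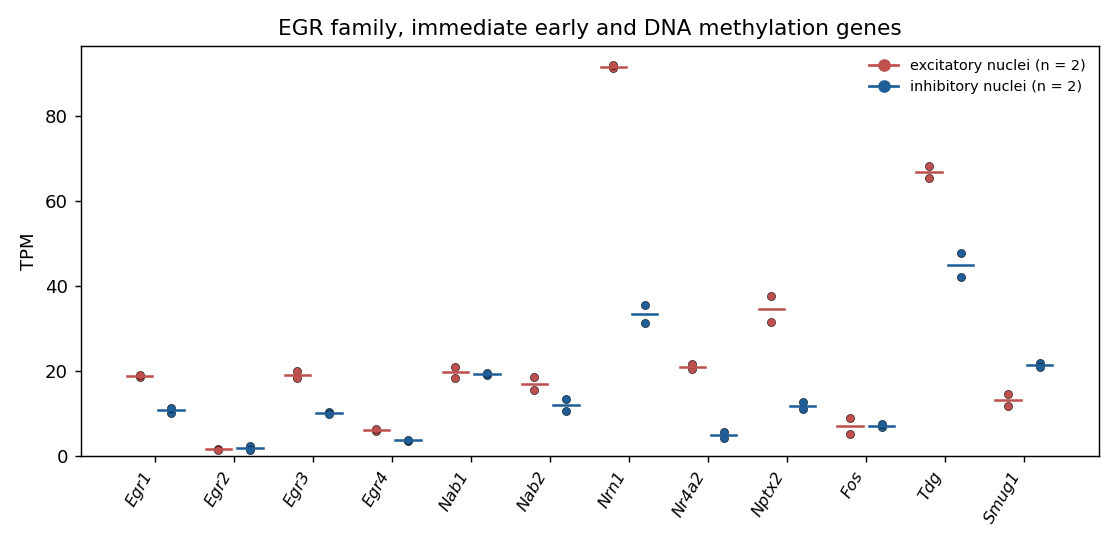
TPM of EGR family, immediate early and DNA methylation genes in each library, with excitatory nuclei in red and inhibitory nuclei in blue (n = 2 each, points for libraries and a line at the mean). Egr1 lies at 18.9 ± 0.189 TPM in excitatory and 10.8 ± 0.865 TPM in inhibitory libraries, and the values of Fos overlap.

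Other genes induced by neuronal activity were higher in excitatory nuclei as well, and Fos was not called. Of 28 immediate early genes tested, 12 were higher in excitatory nuclei and 16 were not called. When adjusted over the list alone, 18 were higher in excitatory and 2 higher in inhibitory nuclei, and the median log2 fold change was 0.78. Camera returned adjusted p = 7.59e-09 for the list, and adjusted p = 0.180 with an estimated correlation. Without the filter on low values, 6 were called. Nr4a2, an orphan nuclear receptor, stood at 21.1 ± 0.829 against 4.94 ± 1.03 TPM and the secreted pentraxin gene Nptx2 at 34.6 ± 4.38 against 11.9 ± 1.25 TPM. The neurite growth gene Nrn1 stood at 91.7 ± 0.485 against 33.4 ± 2.92 TPM and the synaptic scaffold gene Homer1 at 436 ± 34.4 against 186 ± 9.26 TPM. Homer1 is also on the postsynaptic density list. Fos, singled out after its values were seen, stood at 7.06 ± 2.74 against 7.21 ± 0.603 TPM (log2 fold change -0.07 ± 0.30, adjusted p = 0.916).

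Few genes of DNA methylation and histone modification were called. Of 20 DNA methylation and demethylation genes, 1 was higher in excitatory nuclei, the thymine DNA glycosylase gene Tdg at 66.8 ± 1.97 against 45.0 ± 4.08 TPM (log2 fold change 0.56 ± 0.12, adjusted p = 0.0331). The call on Tdg was lost without the filter on low values (adjusted p = 0.0700) and with no trend in the variance prior (0.110). It was also lost when adjusted over the list alone (0 of 20, with 2 toward excitatory and 1 toward inhibitory at an unadjusted p under 0.05; camera adjusted p = 0.997). Smug1, another DNA glycosylase gene, stood at 13.2 ± 1.96 against 21.5 ± 0.599 TPM (adjusted p = 0.0626, and 0.0263 with protein-coding genes only). Gadd45b stood at 10.8 ± 3.17 against 5.93 ± 0.311 TPM and the methyl-CpG binding family gene Mbd3 at 19.3 ± 1.95 against 25.9 ± 3.78 TPM. Of 25 histone acetylation genes, 1 was higher in inhibitory nuclei, the acetyltransferase gene Kat2b at 11.4 ± 2.16 against 34.4 ± 2.57 TPM (1 when adjusted over the list alone; camera adjusted p = 0.505). The deacetylase gene Hdac11 stood at 112 ± 4.31 against 144 ± 14.0 TPM (adjusted p = 0.0965). None of 23 histone methylation genes was called by limma, with 0 toward excitatory and 0 toward inhibitory at an unadjusted p under 0.05 (0 when adjusted over the list alone; camera adjusted p = 0.696). The Polycomb gene Suz12 stood at 37.6 ± 5.26 against 46.4 ± 1.34 TPM.

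Glutamate receptor genes split between the sorts, with 4 of 25 higher in excitatory, 8 higher in inhibitory and 13 not called (9 and 9 when adjusted over the list alone; camera adjusted p = 0.977). The count higher in excitatory was 8 after median ratio scaling, 9 with protein-coding genes only, 8 with the gene length trend removed and 2 with no trend in the variance prior. The NMDA receptor gene Grin2a stood at 221 ± 10.5 against 92.4 ± 4.57 TPM, and Grin2b (0.68), Grm2 (1.16) and Gria3 (0.53), singled out after their values were seen, were the other members higher in excitatory nuclei. Grin2b was not called with no trend in the variance prior, nor was Gria3, whose call was also lost without the filter. The kainate receptor gene Grik1 (41.1 ± 2.89 against 161 ± 14.2 TPM) and Grin3a (22.0 ± 2.43 against 58.5 ± 2.34 TPM) were higher in inhibitory nuclei. The median of this list (0.11) and the camera test pointed toward excitatory and its mean (-0.22) toward inhibitory. GABA and glycine receptor genes were higher in inhibitory nuclei for 6 of 20 and higher in excitatory for 2 (9 and 4 when adjusted over the list alone; camera adjusted p = 0.0734). Camera called this list toward inhibitory after quantile normalization (adjusted p = 0.0373), without the filter on low values (0.0390) and without inhibitory replicate 2 (0.0171), against adjusted p = 0.548 with an estimated correlation. Gabrg1 (-2.29) and Gabra6 (-0.98) were on the inhibitory side, and Gabbr2 (0.41), singled out after its values were seen and not called without the filter or with no trend in the variance prior, on the excitatory side.

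Potassium channel genes, the longest list, held more calls than any other by number though not by share. Of 48 tested, 16 were higher in excitatory and 10 higher in inhibitory nuclei (20 and 13 when adjusted over the list alone). As a set, these genes had a camera adjusted p = 0.0318, and adjusted p = 0.303 with an estimated correlation. Without the filter on low values, 5 were higher in inhibitory nuclei. Kcnv1 (69.4 ± 3.71 against 14.9 ± 1.52 TPM), the sodium-activated channel gene Kcnt2 (1.56 on the log2 scale) and the ERG-type channel gene Kcnh7 (1.38) were higher in excitatory nuclei. The channel-interacting protein gene Kcnip1 was higher in inhibitory nuclei (9.49 ± 0.185 against 53.2 ± 2.51 TPM). The camera call was lost after quantile normalization (adjusted p = 0.0718), without excitatory replicate 1 (0.0842) or without inhibitory replicate 2 (0.0633). Sodium and calcium channel genes had 6 higher in excitatory and 5 higher in inhibitory nuclei of 30 tested (7 and 7 when adjusted over the list alone; camera adjusted p = 0.735). The count higher in excitatory fell to 1 without the filter on low values and to 1 with no trend in the variance prior, which also left 3 higher in inhibitory. The mean (-0.12) differed in sign from the median (0.01) and the camera test. The calcium channel subunit genes Cacna2d1 (355 ± 13.4 against 188 ± 17.8 TPM) and Cacna2d2 (10.2 ± 1.15 against 79.9 ± 8.68 TPM) went opposite ways. The sodium channel genes Scn4b (-1.91) and Scn1a (-0.75, not called with no trend in the variance prior) were higher in inhibitory nuclei.

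Postsynaptic density genes were higher in excitatory nuclei for 9 of 30 and higher in inhibitory for 2 (13 and 2 when adjusted over the list alone). The camera test gave this list an adjusted p = 3.39e-08, and adjusted p = 0.464 with an estimated correlation. The count higher in excitatory was 14 after median ratio scaling or removal of the gene length trend and 5 with no trend in the variance prior. The kinase gene Camk2a stood at 394 ± 53.7 against 139 ± 25.6 TPM and the scaffold gene Dlg1 at 336 ± 23.1 against 167 ± 11.3 TPM. Homer3 (-1.66) and Camk2d (-0.49), the latter singled out after its values were seen and not called without the filter or with no trend in the variance prior, were the members higher in inhibitory nuclei. Of 12 inhibitory synapse genes, 2 were higher in inhibitory nuclei, the GABA transaminase gene Abat (33.7 ± 2.13 against 106 ± 11.03 TPM) and the scaffold gene Gphn (70.4 ± 2.54 against 95.8 ± 2.18 TPM, not called under 5 other settings, median ratio scaling and quantile normalization among them). Adjusted over the list alone, 2 were called (camera adjusted p = 0.169). Presynaptic release genes had 8 higher in excitatory and 7 higher in inhibitory nuclei of 32 (10 and 8 when adjusted over the list alone; camera adjusted p = 0.301). Without the filter, or with no trend in the variance prior, 3 were higher in excitatory nuclei, and with no trend 4 were higher in inhibitory nuclei. The vesicle protein gene Sv2b (1.77), the syntaxin gene Stx1a (2.02) and the vesicle priming gene Unc13b (1.41) were on the excitatory side and its relative Unc13c (-1.92) on the inhibitory side. Synaptic adhesion genes had 4 higher in excitatory and 8 higher in inhibitory nuclei of 32 (9 and 11 when adjusted over the list alone; camera adjusted p = 0.846). The count higher in excitatory depended on the settings, with 9 after median ratio scaling or quantile normalization, 8 after rescaling without top genes and 1 with no trend in the variance prior. The receptor phosphatase gene Ptprd stood at 724 ± 71.2 against 310.4 ± 0.824 TPM. The contactin-associated genes Cntnap2 (-0.99), Cntnap3 (-2.12) and Cntnap4 (-1.27) were all higher in inhibitory nuclei.

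Lists that served as checks of the libraries held few calls. Of 10 nuclear long noncoding RNAs, Miat was higher in excitatory (468 ± 81.2 against 233 ± 38.2 TPM) and Mirg higher in inhibitory nuclei (359.7 ± 16.8 against 499 ± 8.76 TPM), with 1 and 2 calls when adjusted over the list alone (camera adjusted p = 0.553). Both calls were lost without the filter on low values (Miat adjusted p = 0.0691, Mirg 0.0802) and with no trend in the variance prior (0.0664 and 0.138). Mirg overlaps several microRNA genes on its own strand. All genes with a mitochondrial symbol, tested or not, took between 0.0975% and 0.130% of the TPM. The 14 mitochondrial transcripts tested held no limma call (0 toward excitatory and 2 toward inhibitory at an unadjusted p under 0.05, 0 when adjusted over the list alone). Their median log2 fold change was -0.23. Set against all other genes, the list had a camera adjusted p = 0.0473, and adjusted p = 0.527 with an estimated correlation. mt-Nd3 stood at 46.9 ± 4.63 against 60.2 ± 1.86 TPM, mt-Nd5 at 18.1 ± 1.65 against 23.9 ± 0.652 TPM and mt-Co3 at 94.8 ± 8.32 against 115 ± 10.8 TPM. That camera call was lost without excitatory replicate 2 (adjusted p = 0.210), without inhibitory replicate 1 (0.293) and after median ratio scaling (0.0972), a filter of at least 5 TPM (0.0515), restriction to protein-coding genes (0.0681) or removal of the gene length trend (0.0590). No member of the heat shock list (12 tested, 0 toward excitatory and 2 toward inhibitory at an unadjusted p under 0.05, camera adjusted p = 0.311) was called. The mitochondrial chaperonin gene Hspe1 stood at 22.5 ± 4.32 against 33.5 ± 2.54 TPM and was called with protein-coding genes only (adjusted p = 0.0439). No housekeeping gene was called by limma (14 tested, 1 toward excitatory and 1 toward inhibitory at an unadjusted p under 0.05, camera adjusted p = 0.751). Its median (-0.04) differed in sign from the mean (0.03) and the test. The neuronal genes Rbfox3 (129 ± 11.6 against 93.4 ± 13.9 TPM) and Tubb3 (55.7 ± 3.58 against 74.9 ± 15.0 TPM) were on that list. Rbfox3 was called toward excitatory after median ratio scaling (adjusted p = 0.0357), with protein-coding genes only (0.0272) and with the gene length trend removed (0.0288). The 4 sex-linked genes tested held no call either (1 toward inhibitory at an unadjusted p under 0.05), and Ddx3y stood at 37.3 ± 0.617 against 48.7 ± 1.04 TPM (called with protein-coding genes only, adjusted p = 0.0492). Each of these 3 lists had 0 calls when adjusted over the list alone as well.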

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

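Protein-coding restriction and removal of the length trend were chosen after the results were seen. The 1414 genes higher in excitatory and 1725 higher in inhibitory nuclei became 666 and 740 with no filter on low values (37740 genes tested) and 81 and 85 when tested against a log2 change of 1. Under the other alternatives that kept all 4 libraries, excitatory counts ran from 1007 to 1946 and inhibitory counts from 1457 to 2382, and excitatory nuclei held between 40.9% and 54.8% of the calls. With a library left out, with 1 residual degree of freedom, both counts ranged from 0 to 0, as did the calls among distinct list members and among members of the excitatory identity, inhibitory identity, EGR family and immediate early lists. Distinct list members higher in excitatory nuclei fell from 94 to 56 with no filter and to 61 with no trend in the variance prior. EGR family calls went from 2 to 0 with no filter and 1 with no trend, and immediate early calls from 12 to 6 with no filter. Egr1 kept its log2 fold change of 0.75 without the filter and without the trend but lost its call, and with a library left out ranged from 0.68 to 0.83. Among lists with at least 6 calls in a direction, the others whose calls moved by more than 1.5 times without the filter were hippocampal projection (6 to 3), sodium and calcium channel (6 to 1) and presynaptic genes (8 to 3) toward excitatory, and midbrain and hindbrain (8 to 4), monoamine and acetylcholine (9 to 4), hypothalamic peptide (6 to 2) and potassium channel genes (10 to 5) toward inhibitory. A filter of 5 TPM gave 3 for hippocampal projection, 4 for midbrain and hindbrain and 5 for monoamine and acetylcholine genes. No trend in the variance prior gave 1 for sodium and calcium channels and 3 toward excitatory and 4 toward inhibitory for presynaptic genes. Protein-coding genes only gave 13 for midbrain and hindbrain markers, where rescaling let more genes pass the filter. Lists called by camera toward excitatory numbered 8, and 5 to 9 with a library left out. An estimated correlation, tested with 2 residual degrees of freedom, left 0 lists called in either direction. The lowest correlation within a group was 0.967, and 0.933 with a pseudocount of 0.1.

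As a replicate block, the replicate number gave 1946 and 2382 calls. Calls toward excitatory then numbered 10 for glutamate receptors, 16 for postsynaptic density and 10 for synaptic adhesion genes, and the oligodendrocyte list was called toward excitatory (camera adjusted p = 0.0243). The block also called 3 heat shock genes and 6 nuclear long noncoding RNAs toward inhibitory, and the genes Rbfox3 and Mobp toward excitatory. Deviations of same-numbered libraries correlated at 0.0957, over 2 pairs, which does not show whether they share animals, so the number was not used to pair libraries.

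Results that changed direction were uncalled in every case, and the cause was not tested. Camera adjusted p values under the other direction were as follows. After quantile normalization they were 0.977 (oligodendrocyte precursor, microglia, and sodium and calcium channel lists), 0.726 (glutamate receptors) and 0.811 (housekeeping). Median ratio scaling gave 0.957 (DNA methylation) and 0.990 (synaptic adhesion), and no filter 0.971 (DNA methylation and glutamate receptors). Protein-coding genes only gave 0.971 (oligodendrocyte precursor and DNA methylation lists). Removal of the length trend gave 0.921 (DNA methylation and synaptic adhesion) and 0.977 (histone methylation). The direction also changed in some of the 4 fits with a library left out, and over all 4, either direction, adjusted p ranged from 0.446 to 0.749 (oligodendrocyte precursor), 0.427 to 0.582 (microglia), 0.769 to 0.905 (DNA methylation), 0.125 to 0.900 (histone acetylation), 0.157 to 0.769 (histone methylation), 0.864 to 0.990 (glutamate receptors) and 0.234 to 0.784 (housekeeping). Log2 fold changes of uncalled genes then ranged from -0.38 to 0.0493 (Egr2), -0.42 to 0.29 (Fos), -0.0638 to 0.12 (Nab1), -0.15 to 0.00743 (Gpr151) and -0.64 to 0.64 (Cd247), and quantile normalization gave 0.0376 for Fos and 0.0217 for Gpr151. Among other values of named genes with all libraries kept, 1352 stayed on their side of the threshold in the same direction, 47 lost a call and 8 gained one. That tally leaves out the test against a log2 change of 1. Calls lost without the filter, besides Egr1, were those on Avp, Camk2d, Cerkl, Dcn, Egr3, Gabbr2, Gphn, Gria3, Lct, Miat, Mirg, Nts, Otx2, Pcp4, Prss2, Slc4a4, Tdg, Th, Trbc1 and Uncx, and with no trend in the variance prior Camk2d, Cerkl, Gabbr2, Gphn, Gria3, Grin2b, Miat, Mirg, Pcp4, Scn1a, Slc4a4 and Tdg.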

Other observations

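Of the comparisons below, those of scaling, of the non-neuronal share and of heat shock genes, and the gene family tests, were chosen after the results were seen. Those of the further glutamatergic set and of T cell genes were not.

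Chemokine genes of the Ccl19, Ccl21 and Ccl27 kind stood higher in excitatory nuclei. Of 18 Ccl genes tested, 11 were called higher in excitatory nuclei, and all 11 lie on chromosome 4 or on unplaced scaffolds, while 0 of 4 Ccl genes on other chromosomes were called by limma. Ccl27b, singled out after its values were seen, stood at 19.1 ± 0.178 against 3.61 ± 0.819 TPM. Many of these genes are near-identical copies that can share reads, so their values are uncertain and do not count as 11 separate genes. Among 259 families of at least 8 tested symbols with a shared stem, camera called the Ccl and Trbj families (adjusted p = 2.04e-07 for each). With an estimated correlation camera called neither, at adjusted p = 0.999 for every family. Olfactory receptor genes, a large sensory receptor family, had 9 of 38 tested members higher in excitatory and 1 higher in inhibitory nuclei (camera adjusted p = 0.261 over the 32 with a unique stem). Fold changes showed no steady rise or fall with gene length across genes (Spearman rho = -0.00409, genes not being independent replicates). Calls gained after removal of the length trend can therefore also reflect its shift of the overall median. Genes spanning over 100 kb held 315 calls toward excitatory and 369 toward inhibitory among 2421 tested.

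Thalamic and cerebellar granule markers, which include genes of glutamatergic neurons, were higher in inhibitory nuclei for 17 members. Of the tested members, 4 of 11 thalamic and 4 of 15 granule cell markers are also on another list. Among these are Slc17a6 (excitatory identity) and Reln (interneuron subclass), so not every call points to glutamatergic neurons or is separate from the results above. Under each of 4 other scalings, at least 17 members were called. These were median ratio, quantile, rescaling without mitochondrial and top genes and rescaling over protein-coding genes. They left the median log2 fold change of all tested genes between -0.07 and -0.006, against list medians of -1.57 and -0.98. Changes that small could hardly have removed the calls, so they do not decide whether scaling was the cause. A candidate explanation is that glutamatergic nuclei from outside the telencephalon entered the inhibitory sort: in a further set of 17 such markers, 10 were tested, 10 lay below 0, 4 were called higher in inhibitory nuclei and the median was -1.20. Its most abundant tested genes in inhibitory nuclei were Amotl1 (5.57 ± 1.10 against 31.9 ± 0.639 TPM), Lhx9 (2.68 ± 0.266 against 12.0 ± 0.142 TPM) and Gpr151 (13.4 ± 0.407 against 14.1 ± 1.15 TPM, above 0 after quantile normalization), and the call on Uncx (adjusted p = 0.0486) was lost under 7 of the other settings that kept all libraries, median ratio scaling (0.0574) and quantile normalization (0.0673) among them. Inhibitory neurons of the same regions also use some of these genes, so a larger share of such inhibitory neurons stays open, and no test here separated it.

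Segments of the T cell receptor beta locus were higher in excitatory nuclei for 12 of 13 tested Trb genes, on chromosome 6, with Trbc2 at 12.5 ± 0.0873 against 0.934 ± 0.0902 TPM and Trbc1 at 4.87 ± 2.65 TPM and listed at 0 in both inhibitory libraries. The joining segments are short (Trbj1-1 spans 41533864 to 41533911) and lie near Trbc1 and Trbc2 on the plus strand. Their values are uncertain, and segments that 1 transcript can cover do not count as 12 separate genes. Trbj1-1 and Trbc1, at 0 in both inhibitory libraries, passed the filter only through the excitatory ones, so the count partly follows from the filter. The neighbours Prss2 (2.38), Ephb6 (108 ± 0.308 against 50.1 ± 0.690 TPM) and Trpv6 (1.33), singled out like the Trb constant genes after their values were seen, were higher in excitatory nuclei too, though the calls on Prss2 (adjusted p = 0.0608) and Trbc1 (0.0566) were lost without the filter on low values and that on Prss2 with a pseudocount of 0.1 (0.0690). T cells in the excitatory sort, which took neuronal nuclei, are argued against by 12 T cell genes from outside the locus, whose median in excitatory libraries was 0.372 TPM, with Cd247 (4.97 ± 0.901 TPM) and Lck (4.26 ± 0.517 TPM) the most abundant. A difference between the neuron types in transcription across this locus stays open, as a hypothesis that was not tested.

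Of 28 immediate early genes tested, 12 were called higher in excitatory nuclei, and 6 without the filter on low values. A larger non-neuronal share in the inhibitory libraries is argued against by the median of 37 glial markers, 0.23 on the log2 scale toward excitatory. A general stress response of the excitatory nuclei is argued against by the heat shock list, whose median log2 fold change was -0.20. The housekeeping list had a median log2 fold change of -0.0380 (SD 0.30 over 14 genes), against 0.78 for these genes and 2.47 for the Trb genes. The median of all tested genes already stood at -0.07, so the housekeeping list was bound to lie near 0. It therefore does not test scaling between libraries as a cause. A difference between neuron types in the resting or activity-driven level of these genes stays open, and the libraries hold no change of activity that would test it.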
